A study of Mus musculus with 6 samples.

How the data were processed

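Polyadenylated RNA of the mouse melanoma line B16-BL6 was profiled by paired-end sequencing that did not keep the strand, in 3 libraries labelled sgControl and 3 labelled sgNdufs4. The libraries came from cells grown under standard culture conditions and were prepared with TRIzol, per the labels' protocols. HISAT2 and the build GRCm38 are named in the submitters' processing notes, without versions. The counting tool, the gene annotation and any filter are not given in the sources used here.

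The deposited table holds CPM values for 22535 gene rows, scaled by the authors to the size of each library. It also holds the authors' fold change, a log2 fold change rounded to 1 decimal, and a p-value per gene. The authors' deposited fold change equalled the ratio of the group means in 13170 of 13170 rows that have one, within a relative tolerance of 1e-06. Their deposited p-value equalled an unadjusted equal-variance test on CPM in 13513 of 13513 rows, within a relative tolerance of 0.01. These columns were used only for comparison.

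Within each library the CPM values were whole multiples of the smallest value above 0, so that read numbers could be recovered. Between 99.98% and 100% of values above 0 came out whole within a tolerance of 0.01. The libraries then held 20090607, 23652793 and 22276307 reads counted in genes for sgControl and 25817509, 23910781 and 25947374 for sgNdufs4. A floor of 3 reads corresponds to between 0.116 and 0.149 CPM in a library. This floor covers counting error only, since the reads carry no molecular identifiers. Replicate libraries differed by more than sampling noise (chi-square per gene of 3.53 to 5.29 within groups and 43.1 to 51.5 between groups), so none was treated as a duplicate. The labels give no statement that the replicates are separate cultures, nor whether each genotype is a clone or a pool. The p-values therefore measure the spread between these libraries, which may be technical, and the genotype cannot be separated from other differences between the cell lines.

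Of the rows, 9022 were at 0 in every library. There were 26 symbols that a spreadsheet had turned into dates, and 25 symbols occurred more than once. These rows were kept as separate rows and none was named. Gene positions came from GENCODE M21 on GRCm38, matched by symbol, and 10969 of the 11063 genes tested had a position.

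The main test was limma on log2(CPM + 0.5) with a mean-variance trend, for genes with a mean of at least 1 CPM over the 6 libraries. It was two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Fold changes given as log2 are on the log2(CPM + 0.5) scale, which understates the change of low genes. The 40 gene lists were fixed before the data were examined and left Ndufs4 out. They were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists, and beside it with camera at an estimated correlation and with fry. The versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.

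The genes named in the text were chosen by a rule set before the data were examined. It takes Ndufs4, the 12 largest rises and the 12 largest falls among called genes with at least 5 CPM in the higher group and groups that do not overlap, without predicted gene models. For each list described it takes up to 4 members with the smallest p-value and up to 1 member that did not pass. It always takes H2-K1, H2-D1, B2m, Tap1, Psmb8, Psmb9 and Nlrc5, and for markers of other cell types the 3 with the highest mean. Some genes that the rule takes are not reported here.

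On simulated data with 10948 genes tested in the same layout, 50 genes each were changed 1.25-, 1.5-, 2- and 4-fold. Of these, limma recovered 54%, 78%, 96% and 96% in turn, with 5 false calls. Far more genes were called in the real libraries, so this run does not test false calls that come from scaling. Camera called 10 of 10 simulated lists in which part of the members were raised 1.5-fold, and 0 of 30 lists without changed members. Lists with smaller changes were not simulated, so power for them was not tested. The simulated genes were drawn independently and the lists at random, so these runs do not test the preset correlation on lists whose genes vary together. On the recovered reads of the real libraries edgeR called 5583 genes, 2723 higher and 2860 lower. Alternatives were another pseudocount, filter, scaling or variance model, a replicate block, each library left out, edgeR and DESeq2 on the recovered reads, and other set tests. After the data were seen, fits without chromosome X, without chromosomes X, 3 and 13, and with each gene centred on its 50 nearest expressed neighbours were added. Change points along each chromosome were sought on genes with a mean of at least 5 CPM and set against 1000 shuffled gene orders. In simulated chromosomes of 300 genes with a shift of -0.8, the change point was found within 10 genes in 100 of 100 runs. Smaller shifts were not simulated, so the placing of smaller steps, such as those on chromosomes 13 and 3, was not tested.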

Results

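RNA sequencing compared B16-BL6 cells, an invasive subline of the B16 mouse melanoma, carrying a control guide RNA (sgControl, n = 3 libraries) with B16-BL6 cells carrying a guide against Ndufs4 (sgNdufs4, n = 3 libraries). Ndufs4 encodes a subunit of complex I of the mitochondrial respiratory chain. The comparison was made to find the transcriptional changes behind the immunogenicity of the sgNdufs4 cells. The libraries held between 20090607 and 25947374 reads counted in genes.

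The targeted gene was lower in every sgNdufs4 library. Ndufs4 (ENSMUSG00000021764.8, chromosome 13, 114287795 to 114388258, minus strand, GRCm38) was at 54.3, 55.0 and 52.4 CPM in the sgControl libraries and at 14.99, 15.98 and 16.84 CPM in the sgNdufs4 libraries. Its mean was 53.9 ± 1.37 CPM (SD, n = 3) in sgControl and 15.9 ± 0.927 CPM (SD, n = 3) in sgNdufs4, a log2 fold change of -1.73 (SE 0.0764, limma adjusted p = 5.9e-16). In the authors' deposited table its fold change was 0.296.

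Of 11063 genes tested with limma, 3514 were higher and 2241 were lower in sgNdufs4, and 426 changed at least 2-fold. As deposited, 61.1% of the calls were higher, whereas TMM scaling gave 2744 higher and 2863 lower genes, or 48.9% higher. The first principal component held 77.7% of the variance and separated the groups. The groups did not overlap in 57.2% of the genes tested, where chance gives 10%.

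Among the genes that fell most was Enah, an actin-regulating protein (chromosome 1, 181896384 to 182019990), which was at 35.2 ± 3.02 CPM (SD, n = 3) in sgControl and had no read in any sgNdufs4 library, which makes it at least 295.8-fold lower against a floor of 3 reads per library. Tns1, a focal adhesion protein (chromosome 1, 73910231 to 74124449), fell from 40.5 ± 1.87 to 0.657 ± 0.179 CPM (SD, n = 3 each). Nqo1, an NAD(P)H quinone oxidoreductase (chromosome 8, 107388225 to 107403206), fell from 21.6 ± 0.386 to 0.705 ± 0.191 CPM (SD, n = 3 each). Zdhhc15, Sdk1, Xlr, Ptprd and Pycard also had no read in any sgNdufs4 library and were at least 138.1-, 103.2-, 98.7-, 80.2- and 58.3-fold lower. Pycard encodes the inflammasome adaptor ASC. Xlr3c, Gpr37, Pla2g2e and Sh3bp4 completed the 12 largest falls, with log2 fold changes of -4.82, -4.03, -3.74 and -3.68. Zdhhc15, Xlr and Xlr3c lie on chromosome X. Xlr and Xlr3c belong to a family of near-identical copies, so that their reads may be split between members.

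Among the genes that rose most was Trpv4, a cation channel (chromosome 5, 114622152 to 114658421), which rose from 0.511 ± 0.529 to 5.02 ± 0.773 CPM (SD, n = 3 each). Usp44, Mid1, Cngb1, Epor, Robo2 and Cttnbp2 rose by 2.45, 2.34, 2.19, 2.17, 2.12 and 2.10 on the log2 scale. Chn1, Als2cl, Gpr85 and Mndal rose by 2.05, 2.04, 2.04 and 1.99 on the same scale. All of these calls had limma adjusted p-values of 4.1e-06 or less.

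Fold changes were not spread evenly over the genome. On chromosome X, 198 of 223 tested genes up to Brwd3 (chromosome X, 108737016 to 108834372) were lower in sgNdufs4, with a median log2 fold change of -0.84, and this segment held 8.84% of all genes called lower. Beyond it, from Hmgn5 on, the 115 tested genes had a median of 0.21. On chromosome 13, which carries Ndufs4, 238 of 338 tested genes from Zscan12 (chromosome 13, 21362820 to 21372289) onward were higher, with a median of 0.40. On chromosome 3, 288 of 421 tested genes up to Slc30a7 (chromosome 3, 115938973 to 116007406) were higher, with a median of 0.32. The median over the other autosomes was 0.05. The medians of each sgNdufs4 library relative to the sgControl mean lay between -0.84 and -0.81 for the X segment. These 3 segments are given below as the lowered X segment and the raised segments of chromosomes 13 and 3. Chromosomes 10 and 15 also had called change points, with medians of the 2 sides 0.24 and 0.31 apart, against 0.21 on chromosome 3. A place outside the 3 segments therefore does not exclude a regional shift.

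**Figure D1:**
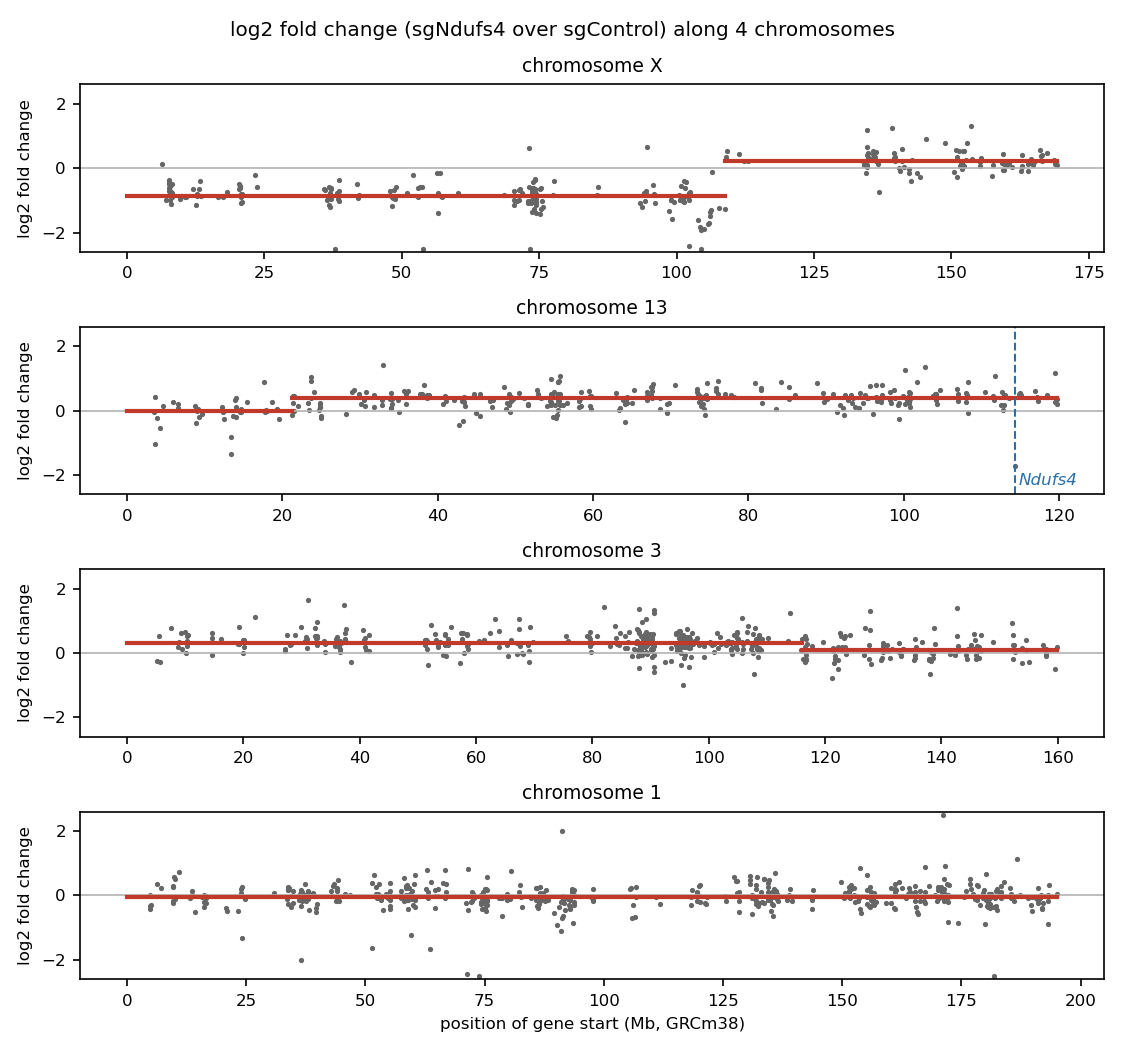
Each point is a gene with a mean of at least 5 CPM, placed by its start in Mb on chromosomes X, 13, 3 and 1 of GRCm38 (x axis) and by its log2 fold change of sgNdufs4 over sgControl on log2(CPM + 0.5) (y axis, with values outside the axis drawn at its edge). Red lines are medians on either side of the change point, or over the chromosome where no change point was called, and the dashed line marks Ndufs4. The X chromosome steps from a median of -0.86 to 0.21, whereas chromosome 1 shows no called step.

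Genes of MHC class I antigen processing and presentation, the pathway that displays peptides on class I molecules at the cell surface, were higher in sgNdufs4. Of 20 members tested, 14 rose, 0 fell and 6 did not pass, with a median log2 fold change of 0.36 (camera adjusted p = 0.00012, and adjusted p = 0.38 with an estimated correlation). Adjusted over the list alone, 14 rose and 1 fell. The immunoproteasome subunits Psmb8 (chromosome 17, 34197721 to 34201454) and Psmb9 (chromosome 17, 34181987 to 34187764) rose from 8.18 ± 0.934 to 20.4 ± 0.599 CPM and from 0.871 ± 0.135 to 3.23 ± 0.293 CPM (SD, n = 3 each). The class I heavy chains H2-K1 (chromosome 17, 33996017 to 34000347) and H2-D1 (chromosome 17, 35262730 to 35267499) rose from 19.8 ± 2.01 to 37.8 ± 4.24 CPM and from 101.2 ± 5.82 to 142.9 ± 6.55 CPM. Light chain B2m (chromosome 2, 122147686 to 122153083) rose from 253.1 ± 9.14 to 328.4 ± 7.67 CPM. The peptide transporter Tap1, the class I transactivator Nlrc5 and the proteasome activator Psme1 rose by 0.64, 0.66 and 0.68 on the log2 scale. Calr, a chaperone of class I assembly, had a log2 fold change of 0.04 (limma adjusted p = 0.16) and one of -0.14 after regional centring (adjusted p = 0.00045), where 11 members of the list were higher and 2 lower. Class I heavy chains are close paralogs and Psmb9 overlaps Tap1, so their counts without strand are uncertain. None of the members lay in the lowered X segment and 1 lay in the raised segment of chromosome 13.

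Interferon lists did not pass as sets. Of 45 listed type I interferon-stimulated genes 30 were tested, and 15 rose and 6 fell, with a median of 0.18 (camera adjusted p = 0.28). Adjusted over the list alone, 15 rose and 7 fell. The median ranged from 0.10 to 0.24 with a library left out, and after regional centring it was 0.076, with 11 genes higher and 7 lower. Samd9l rose from 12.4 ± 2.03 to 35.3 ± 1.52 CPM (SD, n = 3 each), and Adar, Eif2ak2 and Trim30a rose by 0.42, 0.69 and 1.54 on the log2 scale. Adar, in the raised segment of chromosome 3, was at 0.11 after regional centring and did not pass. Of 33 listed interferon gamma-response genes 14 were tested, and 6 rose and 3 fell, also when adjusted over the list alone. Their median was 0.22 and their mean 0.01 (camera adjusted p = 0.75). In this list the guanylate-binding protein Gbp2 rose by 1.39 and the chemokine Cxcl10 fell by 2.57 on the log2 scale. The gamma list shares Cxcl10 with the chemokine list and Cd274 with the checkpoint list.

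The chemokines and cytokines that could be tested were lower as a set. Of 42 listed, 12 were tested, and 6 fell and 2 rose, also when adjusted over the list alone. The median of the 12 was -0.30 (camera adjusted p = 0.023, and adjusted p = 0.34 with an estimated correlation). Cxcl10 fell from 229.9 ± 9.40 to 38.2 ± 1.35 CPM (SD, n = 3 each), and Ccl5 fell from 6.16 ± 2.05 to 1.21 ± 0.398 CPM (SD, n = 3 each). Both recruit T cells. Csf1 fell by 0.64 and Tgfb2 rose by 1.12 on the log2 scale. The call was lost with a filter of at least 5 CPM, with edgeR and without chromosomes X, 3 and 13.

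Of 29 listed immune checkpoint and natural killer ligands 10 were tested, and 6 rose and 0 fell. Their median was 0.44 (camera adjusted p = 0.049, and adjusted p = 0.34 with an estimated correlation). Adjusted over the list alone, 7 rose. Lgals9, Nectin2, Cd276 and Raet1d rose by 0.57, 0.61, 0.95 and 0.75 on the log2 scale. Raet1d has close paralogs. Cd274, which encodes PD-L1, was at 2.29 ± 0.182 and 2.96 ± 0.302 CPM (SD, n = 3 each, limma adjusted p = 0.23). The set call was lost in 8 of 22 other fits with camera, among them the replicate block and 3 of the fits that left out a library. Of 14 listed genes of MHC class II antigen presentation 5 were tested, and 3 rose and 0 fell (camera adjusted p = 0.099). Adjusted over the list alone, 3 rose and 1 fell. Those that rose were Lgmn, H2-DMb1 and Ctsl, the last in the raised segment of chromosome 13. Of 18 nucleic acid sensing genes tested, 4 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.73). Of 20 NF-kB target genes tested, 5 rose and 6 fell, also when adjusted over the list alone (camera adjusted p = 0.48).

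**Figure D2:**
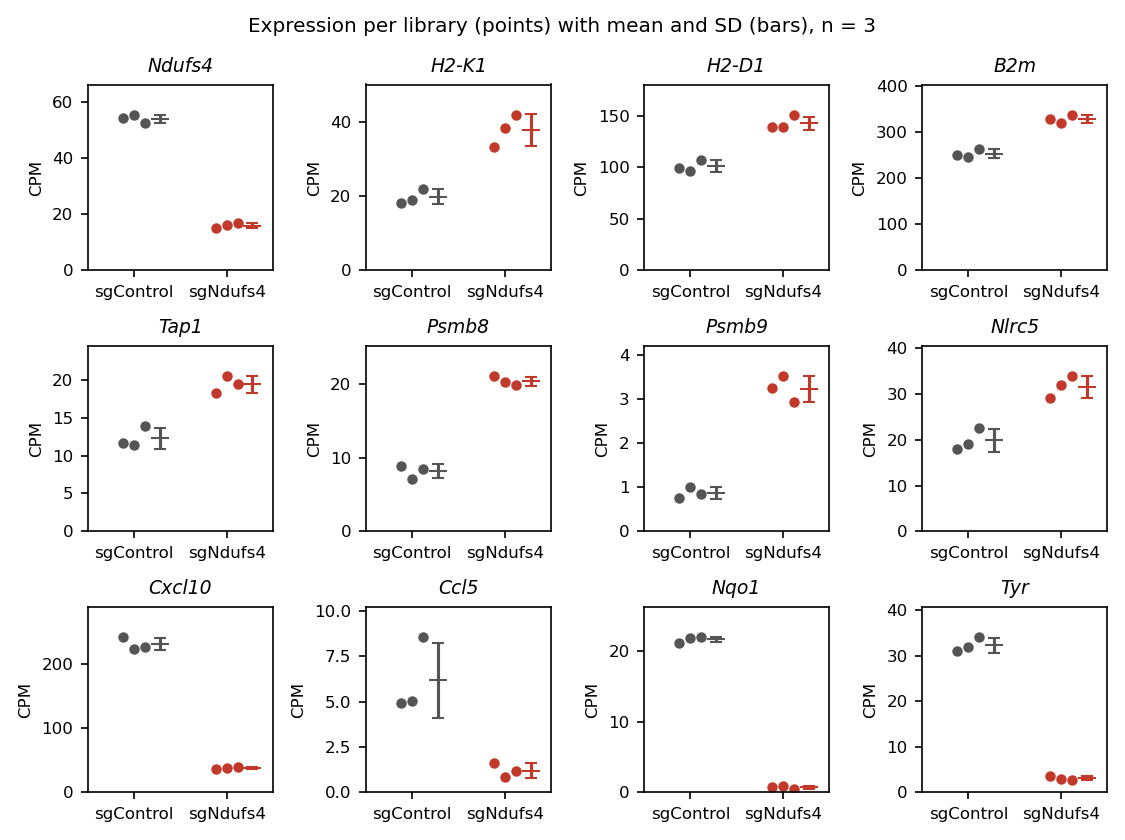
CPM (y axis, from 0) of 12 genes in the 3 sgControl and the 3 sgNdufs4 libraries (x axis). Points are libraries and bars are means with SD (n = 3). In each of these panels the groups do not overlap, with Ndufs4 at 53.9 against 15.9 CPM, H2-K1 at 19.8 against 37.8 CPM and Cxcl10 at 229.9 against 38.2 CPM.

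Mitochondrially encoded mRNAs, which code for subunits of the respiratory chain, were higher. Of 13 mitochondrially encoded mRNAs, 12 rose and 0 fell, also when adjusted over the list alone, with a median of 0.47 (camera adjusted p = 2.3e-07, and adjusted p = 0.34 with an estimated correlation). They took between 2.59% and 2.79% of reads in sgControl and between 3.51% and 3.57% in sgNdufs4. The summed level of all genes with Hist symbols, from the histone clusters whose mRNAs mostly lack a poly(A) tail, was 32.7, 30.4 and 27.4 CPM in sgControl and 46.6, 48.9 and 49.6 CPM in sgNdufs4. The 3 of these genes tested in a fixed list lay in the raised segment of chromosome 13. mt-Co1 rose from 10905 ± 393.1 to 15121 ± 393.4 CPM (SD, n = 3 each), and mt-Nd4, mt-Co2 and mt-Cytb rose by 0.47, 0.65 and 0.33 on the log2 scale. Of 35 tested nuclear subunits of complex I other than Ndufs4, 19 rose and 4 fell, with a median of 0.15 (camera adjusted p = 0.049, and adjusted p = 0.57 with an estimated correlation), and adjusted over the list alone 21 rose and 5 fell. Ndufb5, Ndufs6 and Ndufa9 rose by 0.52, 0.68 and 0.37 and Ndufb11 fell by 0.55 on the log2 scale. Of this list, 5 members lay in the 3 segments, among them Ndufs6, Ndufb5 and Ndufb11, which after regional centring were at 0.28, 0.14 and 0.22 on the log2 scale. The call was lost under TMM scaling, with edgeR and DESeq2, and when Ndufs4 was added to the list. Of 16 complex I assembly factors tested, 4 rose and 1 fell, with a median of 0.16 (camera adjusted p = 0.48). After regional centring 1 of them was higher and 2 were lower. Of 41 tested subunits of complexes II to V, 20 rose and 3 fell (camera adjusted p = 0.051), and with regional centring 12 were higher and 5 lower. Adjusted over the list alone, these last 2 lists gave the same numbers as when adjusted over all genes.

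NRF2 and antioxidant genes were lower. Of 35 tested, 23 fell and 4 rose, also when adjusted over the list alone, with a median of -0.17 (camera adjusted p = 2.3e-07, and adjusted p = 0.16 with an estimated correlation). G6pdx and Pgd, dehydrogenases of the pentose phosphate pathway, fell from 385.2 ± 9.82 to 184.4 ± 4.33 CPM and from 461.8 ± 0.885 to 244.0 ± 4.38 CPM (SD, n = 3 each). Osgin1 fell by 1.01 and Nqo1 by 4.21 on the log2 scale. G6pdx lay in the lowered X segment and was at -0.17 after regional centring.

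Cell cycle genes were lower. Of 32 tested G2 and M phase genes, 18 fell and 2 rose, with a median of -0.20 (camera adjusted p = 5.6e-06, and adjusted p = 0.16 with an estimated correlation), and adjusted over the list alone 20 fell and 2 rose. The mitotic kinases Aurka and Plk1 fell from 231.4 ± 11.5 to 150.1 ± 1.96 CPM and from 331.5 ± 4.31 to 247.9 ± 1.83 CPM (SD, n = 3 each). Mki67 and Bub3 fell by 0.32 and 0.30 on the log2 scale. Of 28 S phase genes, 16 fell and 1 rose, also when adjusted over the list alone, with a median of -0.16 (camera adjusted p = 4.1e-05, and adjusted p = 0.22 with an estimated correlation). The replicative helicase subunits Mcm6, Mcm3 and Mcm5 fell by 0.50, 0.40 and 0.35 on the log2 scale. Pola1, in the lowered X segment, fell by 1.10 on that scale and was at -0.12 after regional centring, where it did not pass. Of 24 tested p53 targets, 15 rose and 1 fell, also when adjusted over the list alone, with a median of 0.27 (camera adjusted p = 0.0070, and adjusted p = 0.34 with an estimated correlation). The cell cycle inhibitor Cdkn1a rose from 163.1 ± 0.734 to 226.7 ± 9.17 CPM (SD, n = 3 each), and Zmat3, Polk and Trp53inp1 rose by 0.77, 0.81 and 1.42 on the log2 scale. Zmat3 and Polk lay in the raised segments of chromosomes 3 and 13 and were at 0.39 and 0.46 after regional centring.

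Of 23 tested chaperones of endoplasmic reticulum stress, 17 rose and 1 fell, also when adjusted over the list alone, with a median of 0.24 (camera adjusted p = 0.00012, and adjusted p = 0.34 with an estimated correlation). Herpud1, Xbp1, Hyou1 and Manf rose by 0.66, 0.67, 0.31 and 0.38 on the log2 scale, and none of the list's members lay in the 3 segments. Of 24 tested genes of cholesterol biosynthesis, 15 fell and 4 rose, also when adjusted over the list alone, with a median of -0.28 (camera adjusted p = 0.0019, and adjusted p = 0.34 with an estimated correlation). Sqle fell by 0.38 on the log2 scale, and lies on chromosome 15 beyond its change point, where the median was -0.16. Ebp and Nsdhl, in the lowered X segment, fell by 0.89 and 1.07 on that scale, and were at -0.12 and -0.17 after regional centring, where they did not pass.

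Of 32 tested genes of melanocyte differentiation and pigmentation, 16 fell and 9 rose, also when adjusted over the list alone, with a median of -0.10 (camera adjusted p = 0.0097, and adjusted p = 0.57 with an estimated correlation). Tyr, the rate-limiting enzyme of melanin synthesis, fell from 32.3 ± 1.57 to 3.10 ± 0.436 CPM (SD, n = 3 each). Mlph, Gpnmb and Ptgds fell by 1.11, 0.55 and 1.56 on the log2 scale. The set call was lost under quantile normalization, at a median of -0.093 and an adjusted p of 0.053. None of the list's members lay in the 3 segments.

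**Figure D3:**
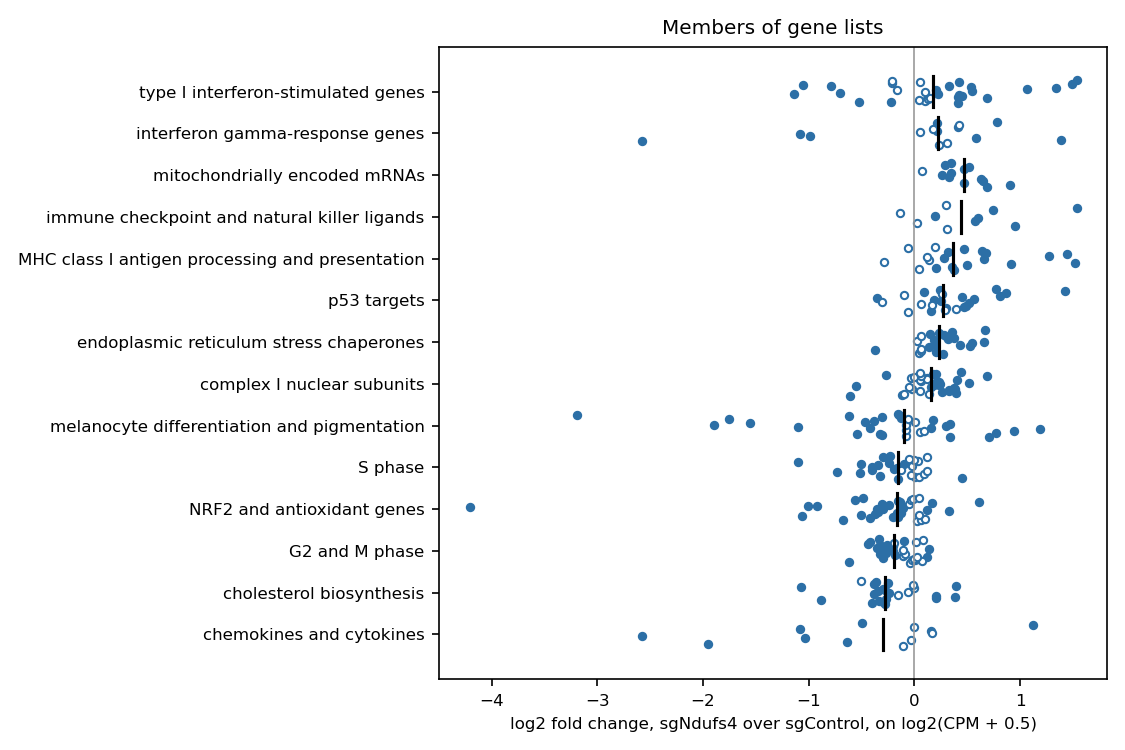
Log2 fold change of sgNdufs4 over sgControl on log2(CPM + 0.5) (x axis) for each tested member of the 12 lists that camera called and of both interferon lists (y axis). Filled points passed a limma adjusted p of 0.05, open points did not, and black bars are medians. The median was 0.36 for MHC class I genes and -0.30 for chemokines and cytokines.

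The remaining lists did not pass camera. Counts of members that rose and fell were 8 and 4 of 18 for melanoma dedifferentiation and invasion (adjusted p = 0.48), 12 and 11 of 50 for ATF4 targets (0.67), 5 and 6 of 19 for mitochondrial chaperones and proteases (0.47) and 6 and 3 of 23 for mitochondrial biogenesis (0.73). They were 8 and 5 of 23 for glycolysis and lactate (0.73), 13 and 2 of 24 for hypoxia-inducible factor targets (0.072), 12 and 12 of 42 for pyruvate dehydrogenase and the TCA cycle (0.48) and 8 and 9 of 32 for histone acetyltransferases, deacetylases and sirtuins (0.29). They were 3 and 7 of 20 for fatty acid synthesis (0.078), 11 and 2 of 23 for fatty acid oxidation (0.12), 6 and 9 of 26 for serine, one-carbon and nucleotide synthesis (0.19) and 11 and 6 of 24 for immediate early genes (0.83). They were 8 and 12 of 33 for lysosome and autophagy (0.12), 6 and 11 of 21 for extracellular matrix (0.099), 19 and 13 of 56 for cytosolic ribosomal proteins (0.84), 16 and 5 of 49 for mitochondrial ribosomal proteins (0.67) and 2 and 1 of 4 for the histone list (0.73). In that list the fall was that of H1f0, a replication-independent linker histone outside the sum given above. With regional centring, 5 mitochondrial ribosomal protein genes were higher and 11 lower. Camera direction and median differed in sign for mitochondrial chaperones, the TCA cycle, nucleic acid sensing, immediate early genes and cytosolic ribosomal proteins.

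Of 22 leukocyte markers 6 were tested, and 0 rose and 2 fell (camera adjusted p = 0.29). Their 3 highest were Cd68 at 4.84 ± 1.43 and 2.64 ± 1.34 CPM, Lyz2 at 3.49 ± 1.33 and 4.34 ± 1.602 CPM and Laptm5 at 1.99 ± 0.672 and 0.900 ± 0.533 CPM (SD, n = 3 each, sgControl first). The fall of Laptm5 did not pass after regional centring. Of 12 fibroblast markers 6 were tested, and 2 rose and 0 fell (camera adjusted p = 0.40). Acta2, a smooth muscle actin, rose from 0.286 ± 0.217 to 4.72 ± 0.785 CPM (SD, n = 3 each). The 3 highest were Col1a2 at 31.5 ± 2.79 and 33.3 ± 2.13 CPM, Pdgfrb at 18.96 ± 0.604 and 30.2 ± 2.30 CPM and Postn at 9.21 ± 0.897 and 8.71 ± 0.108 CPM (SD, n = 3 each). The endothelial list had 1 tested member, Egfl7, which fell by 0.24 on the log2 scale (camera adjusted p = 0.47) and did not pass after regional centring. The keratinocyte list had 2, Cdh1, which fell by 1.01 on the log2 scale, and Krt8 (camera adjusted p = 0.22). Krt8 was at 4.38, 2.75 and 0 CPM in the sgControl libraries, 2.38 ± 2.21 CPM (SD, n = 3), and had no read in any sgNdufs4 library, at least 19.95-fold lower by the means. The median of the 2 genes was -1.50, or -2.66 with Krt8 at this bound.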

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

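The fits without chromosome X, without chromosomes X, 3 and 13, and with regional centring were chosen after seeing the data. The 8 lists whose changes are given in full, those on immunity and complex I, were picked by topic after a first run had been seen. Counts of higher and lower genes stayed within 1.5 times of the main counts in every fit, and Ndufs4 stayed called in the 21 other fits that tested it, at -2.17 to -1.69 on the log2 scale. Leaving out each library gave 3009 to 3401 higher genes, 1952 to 2184 lower genes and 421 to 463 genes changed at least 2-fold. Regional centring gave 2452 higher and 2392 lower genes, and 3933 of the 4033 calls it shared with the main fit kept their direction. Genes changed at least 2-fold dropped from 426 to 218 with a filter of at least 5 CPM, which tested 9655 genes in place of 11063. They numbered 525 with a pseudocount of 0.1 and 337 with a pseudocount of 1. This count therefore depends on genes of low expression. edgeR on the recovered reads called 5583 genes. Depth limits genes near the floor of 3 reads.

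Whether the replicate numbers pair the libraries is not settled. Same-numbered libraries had weak correlations of their deviations, of 0.06, 0.01 and 0.10, though each correlated best with its own number. With the replicate block, 3632 genes were higher and 2309 lower, and the checkpoint and natural killer ligand list, with a median of 0.44, had an adjusted p of 0.053.

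Camera called 12 lists. It called 0 with an estimated correlation, where the medians of 0.15 for complex I, 0.36 for MHC class I, 0.44 for checkpoint ligands and -0.30 for chemokines did not pass. Fry, which does not compare a list with other genes, passed 28. Among them were MHC class II and type I interferon-stimulated genes, at medians of 0.49 and 0.18. Nucleic acid sensing also passed fry, with a median of 0.0465 but a mean of -0.0875, so its median gives no direction. Of the 12, 8 kept their call in every fit but the estimated correlation. MHC class I passed in 22 of 22 other camera fits, with adjusted p from 2.2e-05 to 0.0011. The complex I list did not pass with a filter of at least 5 CPM (0.15), TMM (0.0927), median-of-ratios scaling (0.0925), edgeR (0.0887), DESeq2 (0.0890) or Ndufs4 added to it (0.14), and ranged from 0.12 to 0.19 with a library left out, not passing without sgControl replicate 1 or sgNdufs4 replicate 1. Its adjusted p ranged from 0.0024 to 0.14. The checkpoint list did not pass without a filter (0.20), at 5 CPM (0.43), with quantile normalization (0.37) or DESeq2 (0.41), and ranged from 0.39 to 0.49 with a library left out, not passing without sgControl replicate 1 or 2 or sgNdufs4 replicate 1. Chemokines did not pass at 5 CPM (-0.30), with edgeR (-0.37) or without chromosomes X, 3 and 13 (-0.11). MHC class II passed at 5 CPM (0.49), where only 3 of its genes were tested, Ctsl, Lgmn and H2-DMb1. The list of complexes II to V passed in 7 of 22 other camera fits, with medians from 0.0426 to 0.114 in all. Medians ranged over the fits from 0.0763 to 0.278 for type I interferon-stimulated genes, from 0.144 to 0.327 for interferon gamma-response genes and from -0.164 to -0.0819 for the melanocyte list. Regional centring called 16 lists, the 12 and those of hypoxia-inducible factor targets (adjusted p = 0.044), serine, one-carbon and nucleotide synthesis (0.023), lysosome and autophagy (0.023) and extracellular matrix (0.039). The cause was not tested.

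Medians of lists that were not called changed sign, and most of these were near 0 in the main fit. Larger main medians were 0.11 for melanoma dedifferentiation, 0.085 for glycolysis, 0.16 for complex I assembly factors and 0.53 for the histone list. Under TMM, median-of-ratios scaling, edgeR and DESeq2 in turn, they were -0.0203, -0.0204, -0.0215 and -0.0219 for cytosolic ribosomal proteins and -0.0424, -0.0425, -0.0440 and -0.0443 for mitochondrial chaperones. They were -0.0118, -0.0120, -0.0112 and -0.0115 for mitochondrial ribosomal proteins, -0.0128, -0.0130, -0.0148 and -0.0150 for nucleic acid sensing and -0.0345, -0.0347, -0.0346 and -0.0349 for the TCA cycle. Immediate early genes were at -0.0280 under TMM, -0.0281 under median-of-ratios scaling, -0.0366 under quantile normalization and -0.00694 with array weights, where lysosome and autophagy was at 0.00804. Quantile normalization gave -0.0304 for mitochondrial chaperones and -0.0195 for nucleic acid sensing. Without a filter, ATF4 targets were at 0.000758, melanoma dedifferentiation at -0.0101 and mitochondrial biogenesis at 0.00133.

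Regional centring gave -7.45e-05 for complex I assembly factors, -0.00288 for cytosolic ribosomal proteins, -0.0463 for glycolysis and -0.0963 for mitochondrial chaperones. It gave -0.0359 for mitochondrial ribosomal proteins, -0.0488 for nucleic acid sensing and -0.0387 for the TCA cycle. Without chromosome X, histone acetyltransferases, deacetylases and sirtuins were at 0.0105. Without chromosomes X, 3 and 13, mitochondrial chaperones were at -0.0133, and H1f0, the only gene left of the histone list, was at -0.488. With a library left out, ranges were -0.0104 to 0.00752 for ATF4 targets, -0.0433 to 0.0384 for mitochondrial chaperones, -0.0470 to 0.0150 for mitochondrial biogenesis and -0.0112 to 0.0244 for histone acetyltransferases, deacetylases and sirtuins. They were -0.0452 to 0.137 for immediate early genes and -0.0482 to 0.0164 for lysosome and autophagy. The cause was not tested.

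Regional centring, which removes the shift of neighbouring genes by construction, turned the sign of 11 genes that the naming rule takes from the lists. Rises became -0.0617 for Acad9, -0.0175 for Iars, -0.0243 for Mrps30, -0.153 for Ndufaf2, -0.0461 for Phgdh and -0.0277 for Sdha. Falls became 0.0236 for Hdac6, 0.220 for Idh3g, 0.223 for Ndufb11, 0.0881 for Rpl10 and 0.204 for Rps4x. Of 179 named genes, 18 gained or lost their call without a change of sign in at least 1 fit.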

Other observations

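The tests on the X segment apart from the fit on GC content and transcript length, the test on neighbours of lost genes, the regional centring and the test on leukocyte markers were chosen only after the result was seen, and the outcome of the TMM fit, planned before, had also been seen.

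Gene loss was lopsided. There were 21 genes with a mean of at least 2 CPM in sgControl and at most 3 reads in every sgNdufs4 library, and 3 genes with the reverse. This rule uses the mean, so not all of the lost genes were expressed evenly in sgControl. Krt8 had no read in sgControl replicate 3, and Ptprf was at 2.34 ± 2.22 CPM (SD, n = 3) in sgControl. The lost genes included Arhgef5 and Aim2, a DNA sensor, which were at 5.92 ± 0.525 and 3.29 ± 0.407 CPM (SD, n = 3) in sgControl and without a read in sgNdufs4, at least 49.7- and 27.6-fold lower. The gained genes were Sec16b, Dyrk4 and Pdgfc, at 4.99 ± 0.815, 2.03 ± 0.821 and 2.76 ± 0.850 CPM (SD, n = 3) in sgNdufs4. Genes named in this paragraph were chosen after their values were seen.

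Genes of the proximal X chromosome were lower and genes of most of chromosomes 13 and 3 were higher in sgNdufs4. Library scaling moves every gene of a library alike, and the proximal X median differed from that of the other autosomes by -0.89 (95% bootstrap interval -0.93 to -0.82). After a fit on GC content and transcript length it was -0.91, and genes beyond the change point had a median of 0.21, which argues against silencing of a whole X chromosome. The ratio of sgNdufs4 to sgControl, set against that of the other autosomes, was 0.541 for the X segment and 1.28 and 1.21 for those of chromosomes 13 and 3. A difference in DNA copy number between the lines and regional silencing stay open, since no DNA was analysed here, and whether loss of Ndufs4 itself plays a part was not tested, because genotype and cell line cannot be separated in these groups.

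Of 20 chromosomes tested, 13 had a change point past a Benjamini-Hochberg adjusted p of 0.05, and 5 had one with a difference of at least 0.2 between the medians of its sides. The smallest p that the 1000 shuffled orders can give is 0.001. On chromosome 10 the medians were 0.20 and -0.04, and on chromosome 15 they were 0.14 and -0.16.

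For the 21 against 3 genes, of 20 lost genes with an expressed neighbour within 1 Mb, 5% had that neighbour lowered by at least 2 on the log2 scale, which argues against shared deletions that reach the next gene. Smaller deletions and silencing of single genes stay open, and the genotype itself was not tested against the choice of cell line.

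For the rise of MHC class I genes, regional centring left a median of 0.28 (camera adjusted p = 0.0011), with 11 genes higher and 2 lower in place of 14 and 0, and TMM scaling left 0.30, which argues against a segmental shift or scaling as the whole cause. With an estimated correlation the uncentred list did not pass (adjusted p = 0.38). The summed CPM of leukocyte markers was 23.3, 18.2 and 12.4 in sgControl and 20.4, 11.4 and 8.90 in sgNdufs4, and the difference of the highest values, -2.97, lies within the spread. Reads of Cd14 numbered 14, 6 and 0 in sgControl and 23, 15 and 20 in sgNdufs4, and those of Ptprc 4, 15 and 1 against 21, 3 and 0. A small share of leukocytes, a response to loss of Ndufs4 and a difference between the lines unrelated to it stay open.

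The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split, 1 of 10, gave 3514 higher, 2241 lower and 426 genes changed at least 2-fold, and the highest of the other splits gave 0 for each with limma. In those splits limma called between 60 and 157 genes at an unadjusted p under 0.05, and edgeR called 0. Each of those splits mixes libraries of both labels within its groups, so the difference between the labels adds to the spread within groups. Their low counts follow from this and are no measure of how many genes would be called by chance.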
